A study of Homo sapiens with 50 samples.

How the data were processed

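RNA from ARPE-19, an established line of human retinal pigment epithelial cells, was measured on 50 arrays of the Affymetrix Human Gene 1.0 ST type, which read each transcript through probes spread along its exons. The cultures grew on glass cover slips in medium with 5 or 22 mM glucose and were either photocoagulated with a green frequency-doubled laser or left as controls, and RNA was taken 2, 6 or 24 h later. Because this line lacks pigment in culture, black paper lay beneath each cover slip to absorb the laser energy, and fresh medium was added after the shots. Per the labels, this paper and medium belong to the laser treatment; whether control cultures received them is not stated. A further control grown with mannitol, a sugar alcohol that raises osmolarity, was sampled at 24 h. Replicates were taken from the labels, and each array carries a culture number. These numbers fall into runs, and the 6 h control cultures (125 to 135) share no run with the 6 h laser cultures (4 to 53). Whether numbers stand for independent cultures, plating days or passages is not stated, so the p-values measure the spread between arrays whose independence is not given. Each culture number occurs once and pairs no laser culture with a control.

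The deposited table holds log2 signal values per transcript cluster, called a feature here. The authors made them with Affymetrix Expression Console 1.1.2, per the submitters' processing notes, which do not give its settings. Values ran from 1.37 to 13.92 and array medians from 6.31 to 6.55. The SD of the differences between replicate arrays had a median of 0.235 over the pairs and a maximum of 0.550, against a median of 0.328 for pairs from different groups. Signal over background was not stated, so differences at low signal are differences of signal. Arrays give no counts, and the number of arrays per group limits the precision. Of 33297 features, 4428 lacked values on the 6 arrays of 5 mM glucose at 2 h, which left 28869 complete ones. The platform table paired 21214 features with genes, of which 19460 carried 1 gene and 1754 several. The 19310 complete features of 1 gene each were tested, and they cover 18377 genes; this set is narrower than planned by the 150 features of 1 gene that lacked values. HSPA1A and AKR1B1 have no feature of their own and were not analysed here as single genes. Gene names came from the platform table and were matched by Entrez identifier to the reference table, and coordinates are those of GRCh38 genes in that table.

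Group means were fitted with limma 3.58.1 (lmFit and eBayes, 2-sided moderated test) in R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method over the 19310 features at a threshold of 0.05. Laser effects and their change with time were fitted within each glucose level, on 22 arrays at 5 mM and 24 arrays at 22 mM. Glucose, mannitol and glucose by laser effects were fitted on all 50 arrays. Tests of 26 gene lists used limma's camera at a preset correlation of 0.01 and again with an estimated correlation, and limma's fry; adjustment ran over the lists of each comparison. A list holds the feature with the highest mean for each gene. The mitochondrial RNA list had 0 measured members and gave no result. The comparisons, tests, lists and alternatives were chosen before the data were examined, apart from those named next. Lists of aryl hydrocarbon receptor targets, clock genes and zinc finger (ZNF) genes were added after the data were seen, as were fits with the array median as a covariate, with runs of culture numbers as a block, within single runs at 24 h, and with the culture series as a block for glucose by laser at 6 h. The same block was also fitted to the laser effects at 6 h, and those fits were dropped because the 6 h controls are a series of their own, which leaves the effect not estimable. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9, and tables were read with data.table, version 1.17.8.

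Genes were named by rule. In each comparison these were up to 8 with the largest rise and up to 8 with the largest fall among those past the threshold. From each list that passed its test or held a member past the threshold, up to 4 members with the smallest adjusted p were added. Where nothing passed, the 3 features with the smallest p are given as values only. HSPA6, DNAJB1, ATF3, TXNIP, VEGFA, TNFSF10, CXCL8 and RPE65 were looked up in every comparison, as HSPA1A and AKR1B1 would have been. A gene with several features is represented by the one with the highest mean over all arrays. Genes named outside this rule were chosen after their values were seen and are marked as such where they appear. Errors beside log2 differences are standard errors (SE) of the fit, and those beside group levels are SDs.

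The fits were tested on simulated data with changes planted in known features. Real arrays also differ by run of culture numbers, so recovery there may be lower. At a planted log2 change of 1, laser comparisons at 5 and 22 mM recovered 93.3 and 93.3 percent of changed features at 2 h. At 6 h these were 95.0 and 98.3 percent, and at 24 h 98.3 and 95.0 percent. At 0.5 the same comparisons recovered 47.5, 58.8, 56.2, 65.0, 65.0 and 62.5 percent. Glucose by laser at 2, 6 and 24 h gave 91.7, 96.7 and 88.3 percent at 1, and 26.2, 36.2 and 40.0 percent at 0.5. For the change of the laser effect with time (2 to 6 h and 2 to 24 h at 5 mM, then at 22 mM), 83.3, 83.3, 86.7 and 88.3 percent were recovered at 1, and 23.8, 12.5, 32.5 and 17.5 percent at 0.5. Glucose at 2, 6 and 24 h gave 90.0, 96.7 and 98.3 percent at a change of 1, and mannitol 100 percent.

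Each result was recomputed with arrays centred on their medians, with quantile normalization, without the dimmest 33.3 percent of features, with all complete features, with a trend and robust option in eBayes, on all 50 arrays or only the groups compared, with the culture series as a block at 24 h, on 24 h arrays of culture numbers under 45, and without each array in turn. The number of calls was also counted for other splits of the same arrays. Features of several genes (1752 complete) and with no gene name (7807 complete) were left out of the tests and counted apart.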

Results

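Transcript levels in ARPE-19 cells were measured 2, 6 and 24 h after photocoagulation, in 5 or 22 mM glucose. Each combination of laser or control, glucose level and time had 4 arrays, except 3 for each 5 mM group at 2 h. Mannitol controls added 4 arrays at 24 h, which gives 50 arrays in 13 groups. The series was designed to compare laser-treated with control cells separately at each glucose level.

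At 2 h after photocoagulation in 5 mM glucose, a small set of early response genes was higher in the laser arrays. EGR1, a growth- and injury-responsive transcription factor (feature 8108370, GRCh38 chromosome 5, 138465479 to 138469303), rose 5.07-fold, by 2.34 ± 0.36 (SE) on the log2 scale (limma adjusted p = 0.00553). It stood at 7.64 ± 0.30 in controls and 9.99 ± 1.21 in laser arrays (SD, n = 3 each). The arrestin-domain gene ARRDC3 rose by 2.07 ± 0.23 (adjusted p = 9.85e-05), and ADM, which encodes the vasodilator peptide adrenomedullin, by 1.37 ± 0.12 (adjusted p = 6.78e-06). HMOX1, the haem-degrading enzyme of the oxidative stress response (feature 8072678, chromosome 22, 35381096 to 35394207), rose 2.04-fold from 7.08 to 8.10 (log2 1.03 ± 0.17, adjusted p = 0.0109). Interferon epsilon (IFNE) fell (adjusted p = 0.00702), and so did CD274, the immune checkpoint ligand PD-L1, by 0.92 ± 0.17 (adjusted p = 0.018).

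In total 30 features passed at 5 mM at 2 h, of which 20 rose and 10 fell. Of 26 immediate early genes, 1 rose (EGR1) and 25 did not pass, against 5 up and 1 down adjusted over the list alone. Immediate early genes as a list had adjusted p = 2.10e-04, and adjusted p = 0.735 with an estimated correlation. HMOX1 was the 1 riser of 18 oxidative stress genes, also adjusted over the list alone. Oxidative stress as a list had adjusted p = 0.00684, and adjusted p = 0.735 with an estimated correlation. In the unfolded protein list 1 of 22 rose, PPP1R15A, which directs the dephosphorylation of an initiation factor (log2 0.67 ± 0.10), and 1 rose and 1 fell adjusted over the list alone. Unfolded protein genes as a list had adjusted p = 0.0205, and adjusted p = 0.735 with an estimated correlation. ADM was the 1 riser of 21 hypoxia and glycolysis genes, over all genes and adjusted over the list alone. Hypoxia genes as a list had adjusted p = 0.0357, and adjusted p = 0.735 with an estimated correlation.

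The proapoptotic BCL2L11 was the 1 riser of 16 death and survival genes at 5 mM at 2 h (log2 0.74 ± 0.11), and IRF1 that of 21 interferon genes (0.78 ± 0.16). Each was also the 1 riser adjusted over the list alone, and neither list passed (adjusted p = 0.595 and 0.513). The heat shock list had a median of 3.37e-04 and adjusted p = 0.770. In limma 0 of its 23 members passed, over all genes or adjusted over the list alone, while 1197 of all features had an unadjusted p under 0.05. HSPA6, its strictly heat-inducible member, lay at 5.06 in each group. Small nucleolar RNAs, a sign of RNA quality, were higher as a list of 176 (median log2 0.121, adjusted p = 1.04e-05) with 0 members called by limma, over all genes or adjusted over the list alone. This call was lost at adjusted p = 0.735 with an estimated correlation.

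The number of features called at 5 mM at 2 h depended on single arrays. It was 10 without laser replicate 3, and 11, 10 and 4 without control replicates 1, 2 and 3. It was 13 in a fit of only the 6 arrays compared, 47 with all 50 arrays and 50 with all complete features. ARRDC3, ADM and the splicing-related RSRP1 (log2 -0.73 ± 0.10) kept their calls in each of 14 refits. EGR1 and PPP1R15A each lost their call in 2 of these, BCL2L11 in 1, HMOX1 in 4, CD274 in 7 and IRF1 in 8, and IFNE in 2 of 13. Of the lists, hypoxia lost its call in 5 of 9 refits (median 0.035 to 0.110; without laser replicates 1 and 3, control replicate 1 or the dimmest features), and the unfolded protein and oxidative stress lists in 3 each (without the dimmest features, and without laser replicate 3 for the first and laser replicate 2 for the second). The small nucleolar RNAs lost theirs in 2, without the dimmest features as well as with the estimated correlation that each of these counts includes.

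In 22 mM glucose at 2 h, the transcription factor gene FOS rose 5.03-fold (log2 2.33 ± 0.12, n = 4 and 4, limma adjusted p = 1.45e-11). EGR1 rose 3.68-fold, from 8.17 to 10.05 ± 0.30 (SD, n = 4, log2 1.88 ± 0.12, limma adjusted p = 4.85e-10). ADM (1.63 ± 0.14), ARRDC3 (1.20 ± 0.12), the transcriptional coregulator CITED2 (1.01 ± 0.09) and HMOX1 (0.93 ± 0.20, adjusted p = 0.0259) also rose. Transcripts that fell included CD274 (log2 -1.21 ± 0.18), IFNE (-1.03 ± 0.17), RSRP1 (-1.02 ± 0.13) and the splicing kinase CLK4 (-0.90 ± 0.09). Several zinc finger genes fell as well, among them ZNF566 (-0.98 ± 0.13) and ZNF780A (-0.90 ± 0.12).

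Of 136 features called at 22 mM at 2 h, 36 rose and 100 fell. The immediate early list held 3 members that rose (FOS, EGR1 and NR4A3) and 23 that did not pass, against 9 up and 1 down adjusted over the list alone. Immediate early genes as a list had adjusted p = 0.0101, and adjusted p = 0.732 with an estimated correlation. ATF3, a stress-induced member, differed by 0.57 ± 0.17 (adjusted p = 0.147). PLK3 fell among 18 p53 targets (log2 -0.45), against 1 up and 2 down adjusted over the list alone, and the list did not pass (adjusted p = 0.0677). Heat shock genes were lower as a list (median log2 -0.0662, adjusted p = 0.0188), with 0 of 23 called by limma and 1 lower adjusted over the list alone. Their call was lost at adjusted p = 0.732 with an estimated correlation. The small nucleolar RNAs, higher at 5 mM, were lower here (median log2 -0.0515, adjusted p = 9.82e-04), with 1 up and 2 down, or 3 up and 11 down adjusted over the list alone. That call was lost at adjusted p = 0.732 with an estimated correlation.

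Among 65 ribosomal protein genes, RPL31 fell at 22 mM at 2 h, over all genes and adjusted over the list alone (median -0.00948). Ribosomal protein genes as a list had adjusted p = 0.0335, and adjusted p = 0.771 with an estimated correlation. Endothelial markers, for another cell type, were higher as a list of 12 (median log2 0.178, adjusted p = 0.0188), with 0 called by limma and 1 higher adjusted over the list alone. That list had adjusted p = 0.732 with an estimated correlation. Its means of 4.637 in controls and 4.813 in laser arrays are not shown to be above background. The count of 136 (laser effect 22 mM 2 h) was 462 without laser replicate 3, 292 without control replicate 2, and 67 and 69 without laser replicates 2 and 4. It was 59, 60 and 59 without control replicates 1, 3 and 4, and 62 in a fit of only the 8 arrays compared. FOS, EGR1, ADM, ARRDC3, CITED2, CD274, RSRP1, ZNF566, ZNF780A and CLK4 kept their calls in all 16 refits. HMOX1 lost its call in 7 of 16, PLK3 in 9 of 16, RPL31 in 3 of 16 and NR4A3 in 8 of 15. The heat shock list lost its call in 5 of 11 refits (median -0.101 to -0.035; without laser replicates 1 and 2, control replicate 3 or the dimmest features). The endothelial list and the ribosomal protein list, whose median ran from -0.035 to 0.014, lost theirs in 4 (without laser replicate 1, control replicate 3 or the dimmest features). The small nucleolar RNAs lost theirs in 3 (median -0.103 to -0.007; without laser replicate 1 or the dimmest features).

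**Figure D1:**
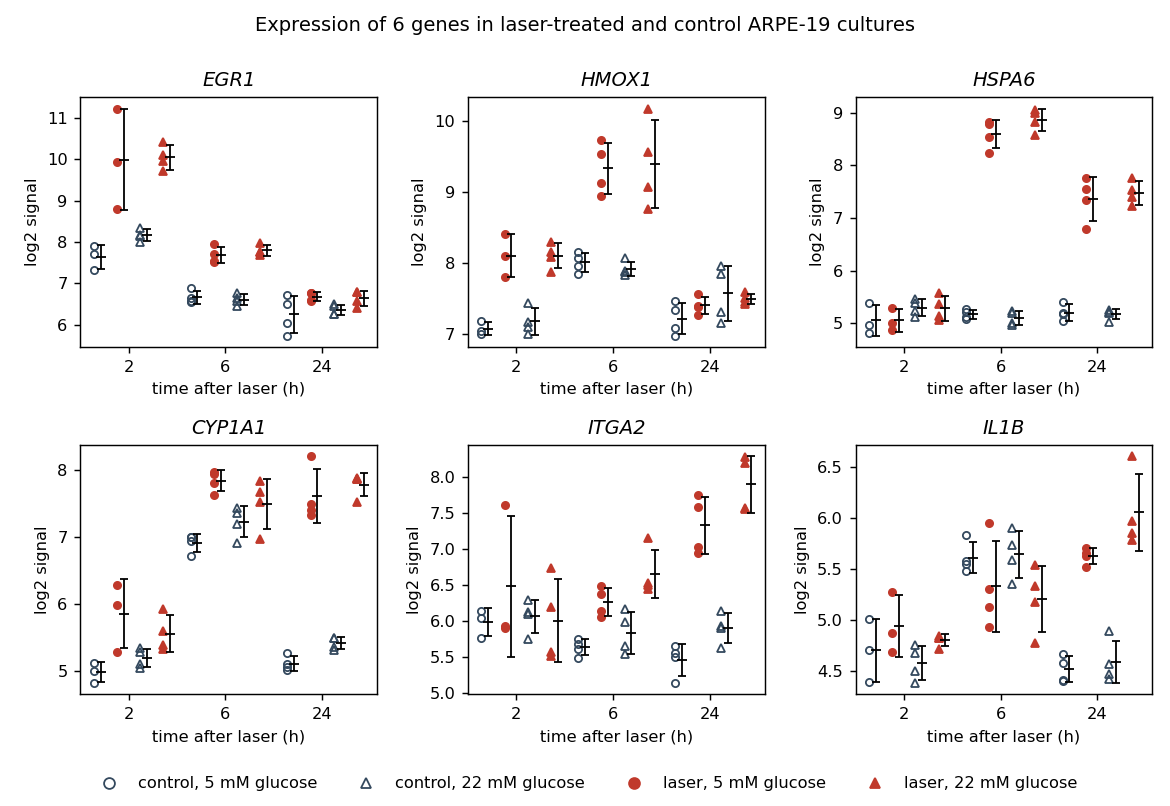
Log2 signal of 6 genes on each array (y axis) against hours after the laser (x axis); open symbols are control and filled symbols laser cultures, circles 5 mM and triangles 22 mM glucose, and bars give the group mean ± SD (n = 4, or 3 at 5 mM at 2 h). HSPA6 lay at a mean of 5.06 in laser arrays of 5 mM at 2 h, 8.60 at 6 h and 7.36 at 24 h, while the means of its control groups stayed between 5.06 and 5.30.

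At 6 h the transcript of HSPA6, a heat-inducible chaperone of the HSP70 family (feature 7906764, chromosome 1, 161524540 to 161526894), was higher in the laser arrays. At 5 mM its signal rose from 5.17 to 8.60 ± 0.27 (SD, n = 4, log2 3.43 ± 0.17, limma adjusted p = 6.19e-11). At 22 mM it rose from 5.10 to 8.86 ± 0.22 (SD, n = 4, log2 3.76 ± 0.12, limma adjusted p = 2.16e-16). HMOX1 rose 2.50-fold at 5 mM and 2.78-fold at 22 mM (log2 1.32 ± 0.15 and 1.48 ± 0.20). Genes for DNA replication were lower, such as CCNE2, the cyclin E2 of the G1 to S transition (feature 8151871, chromosome 8, 94880224 to 94896693). It fell from 8.02 to 6.30 at 5 mM (log2 -1.72 ± 0.35, adjusted p = 0.0203) and from 7.85 to 5.86 at 22 mM (-1.99 ± 0.26, adjusted p = 9.5e-05). The serine synthesis enzyme PHGDH fell at each level (-1.01 ± 0.16 and -0.83 ± 0.15), as did asparagine synthetase, ASNS (-0.98 ± 0.12 and -0.38 ± 0.10).

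Among heat shock genes at 6 h, 3 of 23 rose at 5 mM and 9 adjusted over the list alone. Heat shock genes as a list had adjusted p = 1.58e-04, and adjusted p = 0.323 with an estimated correlation. At 22 mM 6 of 23 rose, and 6 rose and 1 fell adjusted over the list alone. There the list had adjusted p = 8.55e-05, and adjusted p = 0.282 with an estimated correlation. Besides HSPA6 the risers included the co-chaperone DNAJB1 (0.54 ± 0.09 at 5 mM and 0.42 ± 0.10 at 22 mM) and, at 22 mM, HSPH1 (0.37 ± 0.10). The unfolded protein list was higher at 5 mM (median 0.206), although the 2 of 22 members past the threshold, ASNS and TRIB3, fell. Adjusted over the list alone, 5 rose and 2 fell, and the list had adjusted p = 0.00993, and adjusted p = 0.553 with an estimated correlation. At 22 mM HERPUD1 (0.50 ± 0.11), DNAJB9 (0.63 ± 0.15) and CALR (0.23 ± 0.07) rose and ASNS fell, the same number adjusted over the list alone. This list (median 0.177) had adjusted p = 7.95e-07, and adjusted p = 0.282 with an estimated correlation.

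In the immediate early list at 6 h, ID1 (0.61 ± 0.11) was the 1 riser of 26 at 5 mM, against 4 up and 1 down adjusted over the list alone. The 5 mM list had adjusted p = 0.00414, and adjusted p = 0.512 with an estimated correlation. At 22 mM 5 rose, with EGR1 at 1.19 ± 0.12, FOS at 0.69 ± 0.12 and IER3 at 0.66 ± 0.16, against 6 up and 1 down adjusted over the list alone. The 22 mM list had adjusted p = 9.81e-04, and adjusted p = 0.282 with an estimated correlation. Of 18 p53 targets 0 were called by limma at 22 mM, over all genes or adjusted over the list alone. The p53 targets as a list had adjusted p = 0.0494, and adjusted p = 0.282 with an estimated correlation (median 0.0228).

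All 20 measured S phase genes were lower at 5 mM at 6 h adjusted over the list alone, and 9 of them over all genes (median log2 -0.877). S phase genes as a list had adjusted p = 2.00e-18, and adjusted p = 0.323 with an estimated correlation. At 22 mM 18 fell over all genes and 20 adjusted over the list alone (median -0.945). This gave adjusted p = 2.57e-22, and adjusted p = 0.282 with an estimated correlation. Examples are CDC6, which loads the replicative helicase (-1.44 ± 0.37 at 5 mM and -1.64 ± 0.25 at 22 mM), and the helicase subunit MCM2 (-0.58 ± 0.14 and -0.79 ± 0.13). Of 22 genes of G2 and mitosis, limma called 0 at 5 mM, where 3144 of all features had an unadjusted p under 0.05, and 22 were lower adjusted over the list alone (median -1.08). Mitotic genes as a list had adjusted p = 1.36e-15, and adjusted p = 0.323 with an estimated correlation. At 22 mM 14 fell, among them CDC20 (-1.26 ± 0.32), KIF11 (-1.34 ± 0.35) and MKI67 (-1.24 ± 0.33), and 22 adjusted over the list alone (median -1.13). That list had adjusted p = 1.32e-12, and adjusted p = 0.282 with an estimated correlation.

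The falls of S phase genes differed between arrays by culture number. The S phase mean of the laser array of culture 4 lay 0.392 below the 5 mM controls, against 1.01 for the other 3 arrays. That of culture 22 lay 0.282 below the 22 mM controls, against 1.20 for the other 3. The laser effect at 6 h could not be adjusted for the series, because the 6 h controls form one of their own. Genes of G2 and mitosis differed by culture as well. At 22 mM the array of culture 22 had a mean of 9.185, inside the range of its controls (8.816 to 9.259), and the other 3 laser arrays lay between 7.228 and 7.769. At 5 mM the array of culture 4 lay at 8.543, below its controls (8.990 to 9.176), and the others between 7.722 and 8.043.

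**Figure D2:**
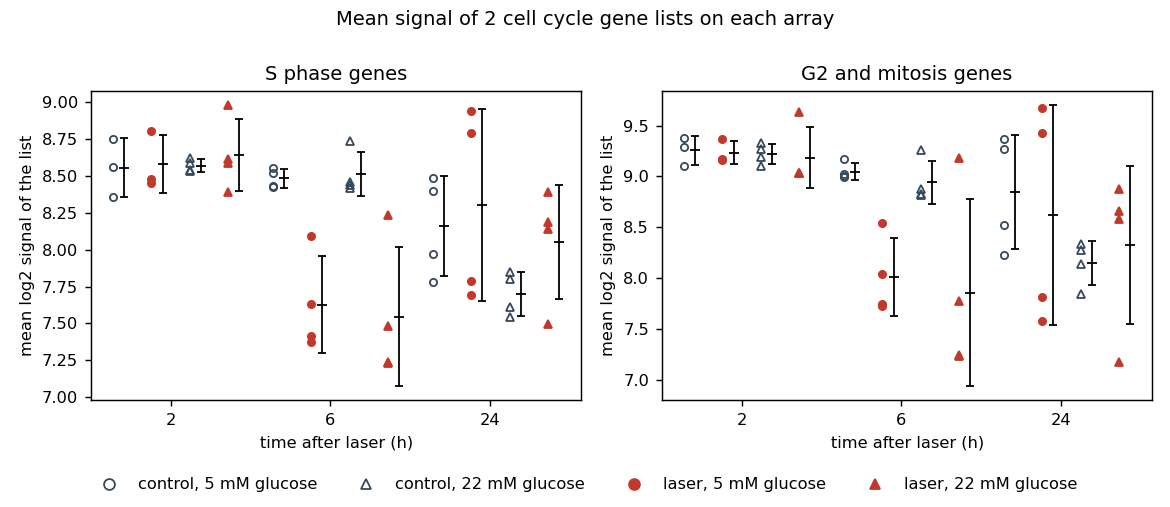
Mean log2 signal of the 20 S phase genes (left) and 22 genes of G2 and mitosis (right) on each array (y axis) against hours after the laser (x axis); open symbols are control and filled symbols laser cultures, circles 5 mM and triangles 22 mM glucose, and bars give the group mean ± SD (n = 4, or 3 at 5 mM at 2 h). At 6 h the 5 mM S phase means of control arrays lay between 8.43 and 8.56 and the laser array nearest to them at 8.09, and at 22 mM the nearest laser array lay at 8.23 against controls from 8.42 to 8.74.

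Targets of ATF4 in the amino acid response list fell at 6 h in 5 of 15 members at 5 mM, over all genes and adjusted over the list alone (median -0.205). They included ASNS, PHGDH, CTH (-0.93 ± 0.15) and SHMT2 (-0.53 ± 0.10). The amino acid list had adjusted p = 7.10e-06, and adjusted p = 0.323 with an estimated correlation. At 22 mM 1 rose and 4 fell, over all genes and adjusted over the list alone. The list did not pass there (adjusted p = 0.847), with a median of 0.00236 and a mean of -0.0732. The 6 h controls had list means of 8.912 at 5 mM and 8.603 at 22 mM. Control means were 8.192 and 8.157 at 2 h, and 8.109 and 8.044 at 24 h. The 6 h laser arrays (8.568 and 8.530) also lay above these. The 6 h controls form a run of culture numbers of their own, so this fall is relative to those controls only. Matrix and mesenchymal genes were higher as a list at 5 mM (median 0.271), with 0 of 22 called by limma and 2 higher adjusted over the list alone. Matrix genes as a list had adjusted p = 0.00198, and adjusted p = 0.553 with an estimated correlation. At 22 mM COL5A1 (0.77 ± 0.18) and ITGB1 (0.42 ± 0.10) rose, and 12 members adjusted over the list alone (median 0.320). This gave adjusted p = 1.19e-08, and adjusted p = 0.282 with an estimated correlation. The laser array of culture 22 stood apart from the other 3 in the means of the matrix, unfolded protein and cholesterol lists at 22 mM.

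Growth factors at 22 mM at 6 h held 4 that rose, with PDGFA (0.74 ± 0.16), ANGPTL4 (1.05 ± 0.24) and TGFA (0.42 ± 0.11), and 1 that fell, KITLG (-1.20 ± 0.25). Adjusted over the list alone, 6 of 24 rose and 2 fell. Growth factors as a list had adjusted p = 0.00666, and adjusted p = 0.282 with an estimated correlation. VEGFA differed by 0.52 (adjusted p = 0.582) at 5 mM and 0.81 (adjusted p = 0.0787) at 22 mM. Metallothioneins, which bind metal ions, were lower as a list at 5 mM, where MT1F fell by 0.44, and 2 of 9 fell adjusted over the list alone. Metallothioneins as a list had adjusted p = 0.00275, and adjusted p = 0.323 with an estimated correlation.

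At 22 mM at 6 h 4 interferon genes fell, such as IFIT3 (-0.86 ± 0.17), and IFI44L rose (1.55 ± 0.43), with 1 up and 5 down adjusted over the list alone and no call for the list (adjusted p = 0.711). NFKBIA (-0.55 ± 0.13) and IL6 (-0.48 ± 0.13) fell among 22 inflammatory genes, the same number adjusted over the list alone (adjusted p = 0.847 for the list). MITF (-0.47 ± 0.08), a regulator of pigment cell identity, and the retinol dehydrogenase RDH10 (-0.71 ± 0.13) fell among 19 pigment epithelium genes, again the same number adjusted over the list alone (adjusted p = 0.712 for the list). Hypoxia and glycolysis genes were higher as a list at 5 mM (median 0.0591), with 0 of 21 called by limma and 4 higher adjusted over the list alone. They gave adjusted p = 0.0373, and adjusted p = 0.553 with an estimated correlation. Cholesterol genes were lower as a list at 22 mM (median -0.215), with 0 of 13 called by limma, over all genes or adjusted over the list alone. Cholesterol genes as a list had adjusted p = 0.0456, and adjusted p = 0.667 with an estimated correlation. They lost this call in 6 of 11 refits (median -0.215 to -0.161), among them those without laser replicate 1, control replicates 1 and 2 or the dimmest features and after centring. The hypoxia list at 5 mM lost its call in 6 of 11 (median 0.049 to 0.124), among them those without laser replicates 1 and 2, control replicates 1 and 4 or the dimmest features. The p53 list at 22 mM lost its call in 4 of 11 (median 0.011 to 0.077), among them those without laser replicate 3 and control replicates 2 and 3.

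At 6 h, 362 features passed at 5 mM (laser effect 5 mM 6 h, 229 rose) and 1291 at 22 mM (laser effect 22 mM 6 h, 219 rose, 1072 fell). The split at 22 mM depended on scaling, with 373 up and 487 down after centring and 480 up and 616 down after quantile normalization. At 5 mM centring gave 264 up and 94 down. The 5 mM count was 86, 110 and 77 without laser replicates 2, 3 and 4, and 73, 77 and 88 without control replicates 1, 2 and 4. Without control replicate 3, 89 rose and 44 fell. A fit of only the 8 arrays compared gave 1420, all 50 arrays gave 1053, quantile normalization 554 and the array median as a covariate 1009. The 22 mM count was 2021, 732, 453 and 512 without laser replicates 1 to 4 and 832 and 553 without control replicates 1 and 2. It was 605 in a fit of only the 8 arrays and 1939 with the array median as a covariate. HSPA6 and HMOX1 kept their calls in all 16 refits at each level, and CCNE2 at 22 mM did too, though no refit separates the laser from the culture series at 6 h. At 5 mM CCNE2, TRIB3, MT1F, MCM2 and CDC6 lost their calls in 6, 6, 7, 8 and 10 of 16, and ID1 in 2. At 22 mM CDC20 and HSPH1 lost theirs in 4, KIF11 and TGFA in 5, ASNS in 6, MKI67 in 7, IFI44L in 8 and CALR in 9 of 16, and IL6 in 10 of 15. For IER3, DNAJB9, NFKBIA and ITGB1 this number was 3, for COL5A1 and DNAJB1 2, and for HERPUD1 and FOS 1 of 16.

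At 24 h the largest rise in signal was that of CYP1A1, a cytochrome P450 that metabolises aromatic hydrocarbons (feature 7990391, chromosome 15, 74719542 to 74725528). It rose from 5.10 to 7.61 at 5 mM (log2 2.51 ± 0.18, adjusted p = 8.29e-08), and from 5.41 to 7.78 at 22 mM (2.37 ± 0.15, adjusted p = 4.02e-10). Its relative CYP1B1 (feature 8051583) rose by 1.54 ± 0.16 and 1.17 ± 0.17. HSPA6 was still higher (by 2.15 ± 0.17 and 2.30 ± 0.12). The collagen-binding integrin subunit ITGA2 (feature 8105267, chromosome 5, 52989352 to 53094779) rose by 1.87 ± 0.26 and 2.00 ± 0.23. The alarmin IL33 rose by 1.74 ± 0.30 and 1.72 ± 0.28. IL1B, a proinflammatory cytokine (feature 8054722), rose in signal by 1.11 and 1.47. The control levels of IL1B (4.51 and 4.59), IL33, CYP1A1, HSPA6 and ITGA2 are not shown to be above background, so their log2 differences are differences of signal and no fold is given for them.

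Genes of the plasminogen system were among those that changed at each level at 24 h. Urokinase (PLAU) rose by 1.46 ± 0.29 and 1.37 ± 0.22, tissue plasminogen activator (PLAT) by 0.97 ± 0.23 and 1.00 ± 0.17, and the receptor PLAUR by 0.52 and 0.41. TIMP3, an inhibitor of metalloproteinases, fell by 0.72 ± 0.08 and 0.59 ± 0.11. In the protease and plasmin list 3 of 16 rose and 1 fell at 5 mM, with 6 up and 2 down adjusted over the list alone, and the list did not pass (adjusted p = 0.0960). At 22 mM 6 rose and 2 fell, over all genes and adjusted over the list alone. Protease genes as a list had adjusted p = 0.0227, and adjusted p = 0.452 with an estimated correlation. They also lost this call without laser replicate 4 (median 0.052) or the dimmest features.

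Oxidative stress genes were higher as a list at 24 h. At 5 mM 1 of 18 rose, the cystine transporter SLC7A11 by 1.06 ± 0.25, and 4 adjusted over the list alone. The 5 mM list had adjusted p = 0.00873, and adjusted p = 0.432 with an estimated correlation. It lost its call in 6 of 11 refits (median 0.037 to 0.178), among them those without laser replicates 1 and 2, control replicates 3 and 4 or the dimmest features. At 22 mM 4 rose, over all genes and adjusted over the list alone, among them SLC7A11 (1.43 ± 0.16) and the quinone reductase NQO1 (0.83 ± 0.12). The 22 mM list had adjusted p = 3.45e-06, and adjusted p = 0.0910 with an estimated correlation. Metallothioneins, lower as a list at 6 h at 5 mM, were higher at 24 h. At 5 mM 2 of 9 rose, MT2A (0.34) and MT1G (0.42), and 3 adjusted over the list alone. Metallothioneins as a list had adjusted p = 1.89e-04, and adjusted p = 0.336 with an estimated correlation. At 22 mM 3 rose and 4 adjusted over the list alone. This gave adjusted p = 6.50e-05, and adjusted p = 0.359 with an estimated correlation.

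Hypoxia and glycolysis genes were lower as a list at 24 h. At 5 mM PDK1, which restrains pyruvate oxidation in mitochondria, fell by 0.44 and the mitophagy gene BNIP3 by 0.58, 2 of 21 over all genes and 3 adjusted over the list alone (median -0.185). Hypoxia genes as a list had adjusted p = 2.21e-07, and adjusted p = 0.336 with an estimated correlation. At 22 mM 8 fell and 13 adjusted over the list alone, with PDK1 at -0.68 ± 0.07, BNIP3 at -0.76 ± 0.08 and the aldolase ALDOC at -0.63 ± 0.09 (median -0.280). That list had adjusted p = 2.76e-08, and adjusted p = 0.0793 with an estimated correlation. Of 22 matrix and mesenchymal genes, 3 fell at 22 mM, namely ACTA2, the smooth muscle actin (-0.94 ± 0.18), TAGLN (-1.02 ± 0.29) and COL3A1 (-0.38 ± 0.11), and 1 rose, the mesenchymal regulator ZEB1. The same number passed adjusted over the list alone, and the list did not pass (adjusted p = 0.206).

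Heat shock genes at 22 mM at 24 h held 5 that rose, with HSPH1 (0.44 ± 0.10) and CHORDC1 (0.64 ± 0.15), and 2 that fell, with the small heat shock protein CRYAB (-0.56 ± 0.10). Adjusted over the list alone, 8 rose and 2 fell. Heat shock genes as a list had adjusted p = 5.03e-06, and adjusted p = 0.0910 with an estimated correlation. In death and survival, 2 of 16 rose, with the p53-inducible PMAIP1 at 0.74 ± 0.14, and 3 rose and 1 fell adjusted over the list alone. Survival genes as a list had adjusted p = 0.0280, and adjusted p = 0.0910 with an estimated correlation. S phase genes, lower at 6 h, were higher as a list at 22 mM (median 0.343), with 0 of 20 called by limma and 3 higher adjusted over the list alone. S phase genes as a list had adjusted p = 3.45e-06, and adjusted p = 0.568 with an estimated correlation. The S phase means of cultures 24 to 26 (8.141 to 8.389) lay above the controls 32 and 33 (7.800 and 7.847), while the laser array of culture 57 (7.497) lay below the controls 67 and 68 of its run (7.540 and 7.611). CXCL8 rose at 22 mM by 0.89 ± 0.25 (adjusted p = 0.0376) and differed by 0.80 (adjusted p = 0.124) at 5 mM. The inflammatory list passed at neither level (adjusted p = 0.130 and 0.342), and its median of -0.0518 and mean of 0.067 differed in sign at 22 mM.

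Other lists moved at 24 h with few members past the threshold. At 5 mM the unfolded protein list was higher (median 0.147, 1 of 22 rose, ASNS by 0.59 ± 0.12, and 2 adjusted over the list alone). Unfolded protein genes as a list had adjusted p = 6.10e-05, and adjusted p = 0.336 with an estimated correlation. Pigment epithelium genes were lower at 5 mM (median -0.119), with 0 of 19 called by limma and 1 lower adjusted over the list alone. Pigment epithelium as a list had adjusted p = 0.00193, and adjusted p = 0.336 with an estimated correlation. At 22 mM MITF (-0.37 ± 0.08) and TYR (-0.41 ± 0.11), genes of pigment cells, fell and MERTK rose, as they did adjusted over the list alone (adjusted p = 0.0555 for the list). Cholesterol genes were lower at 5 mM (median -0.233), with 0 of 13 called by limma and 3 lower adjusted over the list alone. Cholesterol genes as a list had adjusted p = 1.40e-04, and adjusted p = 0.432 with an estimated correlation, and lost the call without laser replicate 4 (median -0.107).

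Markers of other cell types and signs of RNA quality also moved at 24 h. At 5 mM leukocyte markers were lower as a list (median -0.115, adjusted p = 0.0467), with 0 of 12 called by limma, over all genes or adjusted over the list alone. They gave adjusted p = 0.432 with an estimated correlation and lost the call in 7 of 11 refits (median -0.250 to -0.057), among them those without laser replicates 1 to 3, control replicates 3 and 4 or the dimmest features. Neuronal markers were lower too (median -0.128, adjusted p = 0.00691), and MAP2 fell by 0.74 as the 1 of 11 past the threshold, over all genes and adjusted over the list alone. This list gave adjusted p = 0.336 with an estimated correlation. Endothelial markers were lower at 22 mM (median -0.194, adjusted p = 0.0498), with 0 of 12 called by limma, over all genes or adjusted over the list alone. Their call was lost at adjusted p = 0.651 with an estimated correlation and in 7 of 11 refits (median -0.288 to -0.144), among them those without laser replicates 1 to 3, control replicate 1 or the dimmest features and after centring. The small nucleolar RNAs were higher at 5 mM (median 0.168, adjusted p = 6.10e-05), where SNORD14E rose, over all genes and adjusted over the list alone. They had adjusted p = 0.432 with an estimated correlation and lost the call without control replicate 3 (median 0.096). At 22 mM they passed as higher (adjusted p = 0.0437, and adjusted p = 0.698 with an estimated correlation), with a median of -0.00752, a mean of 0.0354, and 3 risers, or 2 adjusted over the list alone. This call was lost in 6 of 11 refits (median -0.026 to 0.050), among them those without laser replicates 1 and 2, control replicate 4 or the dimmest features and after centring.

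At 24 h, 248 features passed at 5 mM (laser effect 5 mM 24 h, 175 rose, 73 fell) and 1069 at 22 mM (laser effect 22 mM 24 h, 505 rose, 564 fell). After quantile normalization 142 of 275 fell at 5 mM, and after centring 713 rose and 443 fell at 22 mM. Within single runs of culture numbers that hold both groups, HSPA6 differed by 2.25 at 5 mM (2 against 2 arrays) and by 2.43 (3 against 2) and 2.00 (1 against 2) at 22 mM. CYP1A1 differed by 2.23, 2.34 and 2.47, and PLAU by 1.01, 1.39 and 1.68. The 5 mM count was 136 without laser replicate 3 and 97 and 100 without control replicates 3 and 4. Without control replicate 2, 79 rose and 47 fell. It was 18 in a fit of only the 8 arrays, 462 with all 50 arrays, 476 with the array median as a covariate, 628 with the culture series as a block, 39 with runs as a block and 12 on culture numbers under 45. The 22 mM count was 485, 403, 337 and 2667 without laser replicates 1 to 4 and 526 and 452 without control replicates 1 and 3. It was 498 in a fit of only the 8 arrays, 519 with the array median as a covariate and 38 within cultures 48 to 68. CYP1A1, HSPA6, ITGA2 and IL1B kept their calls in all their refits at each level, as did CYP1B1 at 5 mM. At 5 mM MT1G lost its call in 13, MT2A and PLAT in 12, SLC7A11 in 10, BNIP3 in 9, PDK1, PLAUR and ASNS in 7, SNORD14E in 5, PLAU in 4, MAP2 in 3 and TIMP3 in 1 of 20 refits, and IL33 in 1 of 19. At 22 mM COL3A1 lost it in 14 of 21 (down to -0.047), CXCL8 and TAGLN in 10, ZEB1 in 8, CHORDC1 in 5, MITF and PLAUR in 4, and TYR and MERTK in 9 of 20. CRYAB, HSPH1, NQO1, PMAIP1, TIMP3, BNIP3, PDK1 and ALDOC each lost it in 1 of 21.

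The laser effects at 5 and 22 mM were then compared directly. HSPA6 rose at each level at 6 and 24 h, and the difference between its rises was 0.33 ± 0.21 at 6 h (adjusted p = 0.964) and 0.15 ± 0.21 at 24 h (adjusted p = 0.917). ID2, an inhibitor of differentiation factors (feature 8040103, chromosome 2, 8682056 to 8684461), was the 1 feature whose laser effect differed by glucose at 6 h. Its signal rose by 1.15 ± 0.17 from 5.12 to 6.27 at 5 mM and stood at 6.10 in controls and 5.98 in laser arrays at 22 mM. The level of 5.12 is not shown to be above background, so the difference is one of signal. The difference of -1.27 ± 0.21 (n = 4 per group, limma adjusted p = 0.00502) kept its call in all 24 refits. The amino acid response list also differed at 6 h, its fall being smaller at 22 mM (median 0.190, adjusted p = 1.18e-08). Its call held at adjusted p = 0.0493 with an estimated correlation, with 0 of 15 members called by limma and 2 higher adjusted over the list alone.

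Limma called 0 features for glucose by laser at 2 h and 0 at 24 h, with 2583 and 1046 at an unadjusted p under 0.05. The smallest p at 2 h belonged to SNORD59A, AP1S2 and PMS2 (-1.32, -0.94 and -0.59, adjusted p = 0.165 each) and at 24 h to LINC02520, DMGDH and PDILT (-0.94, -0.69 and -0.66, adjusted p = 0.453). The small nucleolar RNAs as a list differed at 2 h (median -0.159, adjusted p = 1.64e-07), a call lost at adjusted p = 0.802 with an estimated correlation and without the dimmest features. The heat shock list at 24 h was higher in its response at 22 mM (median 0.104, adjusted p = 0.00150), a call lost at adjusted p = 0.618 with an estimated correlation and without laser replicate 4 of 5 mM (median 0.033).

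Across the 19310 features, which are not independent replicates, the log2 laser effects at 5 and 22 mM had a Pearson correlation of -0.155 at 2 h, 0.718 at 6 h and 0.586 at 24 h. Spearman values were -0.268, 0.489 and 0.540. At 2 h 12 features rose and 5 fell at each level (0.0373 and 0.0518 expected). At 6 h 65 rose and 96 fell (2.60 and 7.38 expected), and at 24 h 101 and 40 (4.58 and 2.13). At 6 h both effects used controls of a separate run, which alone could raise these values. Limma called 0 in opposite directions. The correlation was 0.00681 at 2 h without control replicate 2 and 0.328 at 24 h without laser replicate 1 (5 mM).

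The time course was tested as the change of the laser effect from 2 h. HSPA6 gained 3.43 ± 0.26 by 6 h at 5 mM (adjusted p = 2.46e-07) and 3.77 ± 0.18 at 22 mM (adjusted p = 6.5e-13), and ADM lost its early rise (-1.45 ± 0.17 and -1.79 ± 0.19). IFNE, lower at 2 h, moved up by 2.16 ± 0.23 and 1.92 by 6 h, and RSRP1 by 1.29 ± 0.14 and 1.66. At 22 mM the effects on FOS (-1.64 ± 0.18) and EGR1 (-0.69, adjusted p = 0.0274) shrank by 6 h. Those on FAM111B (-2.20) and CCNE2 (-1.78) moved down. By 24 h CYP1A1 had gained 1.63 ± 0.28 at 5 mM (adjusted p = 0.0132) and 2.01 ± 0.21 at 22 mM, and CD274 1.67 and 1.71. At 22 mM ITGA2 gained 2.06, PLAU 1.70 and IL1B 1.25 by 24 h.

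In all, 26 features changed their laser effect from 2 to 6 h at 5 mM (16 up, 10 down) and 644 at 22 mM (time by laser 22 mM 6 against 2 h, 243 up, 401 down). From 2 to 24 h these numbers were 24 (16 up, 8 down) and 1487 (time by laser 22 mM 24 against 2 h, 605 up, 882 down). Centring moved the splits to 9 up and 9 down and 8 up and 11 down at 5 mM (6 and 24 h), and to 381 up and 174 down and 888 up and 712 down at 22 mM. Quantile normalization gave 523 up and 302 down and 610 up and 437 down at 22 mM. The median of all features moved by -0.0994 from 2 to 6 h and by -0.110 from 2 to 24 h at 22 mM.

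S phase genes moved down from 2 to 6 h at each level. At 5 mM limma called 0 of 20, where 1472 of all features had an unadjusted p under 0.05, and 13 were lower adjusted over the list alone (median -0.884). S phase genes as a list had adjusted p = 2.94e-15, and adjusted p = 0.466 with an estimated correlation. At 22 mM 14 fell and 19 adjusted over the list alone (median -0.988). This gave adjusted p = 3.66e-14, and adjusted p = 0.346 with an estimated correlation. Hypoxia and glycolysis genes moved down from 2 to 24 h. At 5 mM the hypoxia list had a median of -0.254 and adjusted p = 3.39e-10, and adjusted p = 0.259 with an estimated correlation. At 22 mM it had a median of -0.319 and adjusted p = 2.16e-06, and adjusted p = 0.135 with an estimated correlation.

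Single arrays changed these numbers. From 2 to 6 h the 5 mM count was 17 and 11 without laser replicates 2 and 3 of 2 h, and 7, 8 and 5 without control replicates 1 to 3 of 2 h. It was 46, 10 and 9 without laser replicates 1 to 3 of 6 h and 10, 11, 11 and 16 without control replicates 1 to 4 of 6 h. The 22 mM count to 6 h (time by laser 22 mM 6 against 2 h) was 423, 337 and 350 without control replicates 1, 3 and 4 of 2 h and 1332, 311 and 360 without laser replicates 1, 3 and 4 of 6 h. From 2 to 24 h the 5 mM count was 10, 93 and 11 without laser replicates 1 to 3 of 2 h and 11 and 8 without control replicates 1 and 3 of 2 h. The 22 mM count to 24 h (time by laser 22 mM 24 against 2 h) was 753, 723, 4020 and 590 without laser replicates 1 to 4 of 2 h and 527, 2739, 543 and 647 without control replicates 1 to 4 of 2 h. It was 496, 412 and 3396 without laser replicates 2 to 4 of 24 h and 570 and 715 without control replicates 1 and 3 of 24 h. HSPA6, ADM, IFNE and RSRP1 kept their calls to 6 h in all their refits, while EGR1 at 22 mM lost its call in 9 of 24 and, to 24 h, CYP1A1 at 5 mM in 3 of 22.

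Glucose alone was compared in control cultures. At 24 h TXNIP, the glucose-induced inhibitor of thioredoxin (feature 7904726, chromosome 1, 145992435 to 145996579), was 2.42-fold higher at 22 mM. It stood at 10.37 ± 0.06 against 9.10 ± 0.79 (SD, n = 4 each, log2 1.27 ± 0.24, limma adjusted p = 0.00933), and its relative ARRDC4 was higher by 0.60 ± 0.15. The chemokine CCL2 (0.85 ± 0.21) and the kinase SGK1 (0.63 ± 0.16) also rose. NPPB, a natriuretic peptide (-0.90 ± 0.18), ADAMTS1 (-0.96 ± 0.22), the nuclear receptor PPARG (-0.73 ± 0.18) and JUN (-0.65 ± 0.16) fell. At 6 h the signal of ID2 was higher by 0.97 ± 0.15 (adjusted p = 8.09e-04) and that of ID1 by 0.64 ± 0.15. This difference in ID2 rests on the same 6 h controls as its glucose by laser effect. Genes of the amino acid response fell at 6 h, with CTH at -1.12 ± 0.19, ASNS at -0.72 ± 0.11 and TRIB3 at -0.75 ± 0.13. At 2 h limma called 0 features, with 506 at an unadjusted p under 0.05. The smallest p belonged to KRT18P55 (0.41), H4C5 (0.38) and UBBP4 (0.37), each with an adjusted p of 1.

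The amino acid response list was lower at 6 h of 22 mM glucose (median -0.193, adjusted p = 1.30e-16), with 2 of 15 down and 4 adjusted over the list alone. Its call held at adjusted p = 0.00111 with an estimated correlation. The call rests on the same 6 h controls as the laser effect on this list, whose means stood above those at 2 and 24 h. The glucose response list, with targets of the sugar sensors MondoA and ChREBP, held TXNIP and ARRDC4 as 2 risers of 14 at 24 h. It had 2 up and 1 down adjusted over the list alone, and did not pass (adjusted p = 0.636). Matrix genes were higher at 24 h (median 0.368, adjusted p = 7.45e-06), with 0 of 22 called by limma and 11 higher adjusted over the list alone. They gave adjusted p = 0.485 with an estimated correlation. The lists of S phase (median -0.482, adjusted p = 6.43e-12) and of G2 and mitosis (median -0.674, adjusted p = 6.67e-13) were lower at 24 h, with 0 members called by limma, over all genes or adjusted over the list alone. Each had adjusted p = 0.485 with an estimated correlation. These lists also differed within the 5 mM controls by culture number, cultures 9 and 10 lying above cultures 28 and 29 by 0.565 in S phase and 0.945 in G2 and mitosis. Within cultures 22 to 39 the S phase mean was 7.823 at 22 mM and 7.878 at 5 mM, and that of G2 and mitosis 8.304 and 8.373 (2 arrays each). Ribosomal protein genes were higher at 6 h (median 0.0976, adjusted p = 2.15e-04), with 3 of 65 up and 16 adjusted over the list alone. Their call was lost at adjusted p = 0.938 with an estimated correlation.

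For glucose, 116 features passed at 6 h (glucose effect 6 h, 106 rose, 10 fell) and 152 at 24 h (glucose effect 24 h, 26 fell, the others rose). After centring 23 passed at 6 h (9 up, 14 down) and after quantile normalization 30 (11 up, 19 down). At 24 h the splits were 82 up and 31 down after centring and 90 up and 60 down after quantile normalization. The 6 h count was 24, 44, 182 and 48 without control replicates 1 to 4 of 5 mM, and 58, 23 and 189 without control replicates 1, 2 and 4 of 22 mM. It was 293 without the dimmest features, 182 with the trend and robust option and 12 in a fit of only the 8 arrays. The 24 h count was 2, 1 and 434 without control replicates 1, 2 and 4 of 5 mM and 1 and 80 without control replicates 3 and 4 of 22 mM. It was 281 without the dimmest features, 83 with the array median as a covariate, 29 with the culture series as a block and 11 with runs as a block. It was 1 on culture numbers under 45 and 0 within cultures 22 to 39 or in a limma fit of only the 8 arrays.

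TXNIP at 24 h differed by 0.61 within cultures 22 to 39 (2 against 2 arrays) and lost its call in 7 of 19 refits (adjusted p up to 0.573). Among these were the refits without control replicate 1 (1.02) or 2 (1.07) of 5 mM and without control replicate 3 of 22 mM (1.29). At 24 h NPPB lost its call in 7, ADAMTS1 and JUN in 10, PPARG in 12, CCL2 and ARRDC4 in 14 and SGK1 in 15 of 19 refits. The smallest values in these refits were -0.473 for ADAMTS1, -0.120 for JUN, -0.291 for PPARG, 0.535 for CCL2, 0.226 for ARRDC4 and 0.325 for SGK1. ID2, ASNS, CTH and TRIB3 at 6 h kept their calls in all 15 refits, and ID1 lost its call in 9.

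Mannitol was compared with 5 mM glucose at 24 h, and the labels do not give the glucose level of the mannitol cultures. IFNE was higher by 1.05 ± 0.17 (n = 4 and 4, limma adjusted p = 0.00669), as were the cell cycle regulator SPDYA (0.85 ± 0.15) and TIPARP, a target of the aryl hydrocarbon receptor (0.52 ± 0.11). Muscle glycogen phosphorylase, PYGM, fell by 0.51. TXNIP differed by 0.48 ± 0.24 (adjusted p = 0.413) and lay at 9.58 ± 0.21 (SD, n = 4). Within cultures 22 to 39 its difference was -0.31 (2 against 2 arrays). Of 10 osmotic stress genes limma called 0, where 2332 of all features had an unadjusted p under 0.05, and 2 were higher adjusted over the list alone. Their median of -0.0292 and mean of 0.0822 differed in sign (adjusted p = 0.230). Matrix genes were higher (median 0.298, adjusted p = 5.70e-06) and small nucleolar RNAs too (median 0.148, adjusted p = 1.11e-06). S phase genes (median -0.371, adjusted p = 9.59e-05) and G2 and mitosis genes (median -0.489, adjusted p = 6.66e-04) were lower. In limma 0 members of these 4 lists passed, over all genes or adjusted over the list alone, and each list had adjusted p = 0.796 with an estimated correlation. The G2 and mitosis list also lost its call without control replicate 1 (median -0.351) or 2 (median -0.311) of 5 mM. Within cultures 22 to 39 the S phase mean was 7.877 in mannitol and 7.878 at 5 mM, and that of G2 and mitosis 8.446 and 8.373 (2 arrays each).

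In all 11 features passed for the mannitol effect 24 h (9 rose, 2 fell). The count was 2, 0 and 4 without control replicates 2, 3 and 4 of 5 mM, and 2, 1, 7 and 3 without mannitol replicates 1 to 4. It was 7 without the dimmest features, 17 with all complete features or the array median as a covariate, 5 with the culture series as a block, 600 with runs as a block and 2295 within cultures 22 to 39. In limma 0 passed on culture numbers under 45 or in a fit of only the 8 arrays. IFNE and SPDYA lost their calls in 4 of 18 refits, PYGM in 10 of 18 and TIPARP in 10 of 19. Glucose at 22 mM against mannitol gave 0 features in limma, with 2192 at an unadjusted p under 0.05. TXNIP differed by 0.79 ± 0.24 (adjusted p = 0.323), and the smallest p belonged to CLEC4M (0.50, adjusted p = 0.132), LINC01512 (0.70) and BPIFA3 (0.56). The glucose and mannitol effects share the 5 mM controls. Their correlation across features was 0.664, against a mean of 0.502 in 20 simulations with shared controls and no effect. It lay between 0.0589 and 0.472 when each effect used other control arrays.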

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

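The tests weighed below for 3 patterns were chosen after those patterns were seen, and a further condition on the S phase tests was added after their result was known; the counts over other splits of the arrays were planned.

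At 6 h genes of DNA replication were lower in the laser arrays, by 0.855 at 5 mM and 0.969 at 22 mM as the mean of the S phase list. If the run of culture numbers that holds most laser arrays were the cause, the laser arrays of cultures 4 and 22, which lie outside that run, should have been within the range of their controls, yet 2 of 2 lay below all controls of their glucose level, and 0.392 and 0.282 below the mean of these controls. If the 6 h controls had been unusually high, they should have exceeded the 2 h controls by at least the size of the fall, and the larger ratio of this excess to the fall was -0.0580. Both values met what had been set beforehand against these causes, but that criterion was too weak, because those 2 laser arrays and the 2 h controls come from other runs than the 6 h controls, and unlasered 24 h cultures also differed between runs, by 0.565 at 5 mM (above the 0.392), 0.248 at 22 mM (below the 0.282) and 0.120 in mannitol. An effect of the laser and a difference between culture runs therefore cannot be told apart for the size of this fall, and a lower rate of cell division after the laser remains a hypothesis that may account for it.

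HSPA6 was higher in laser arrays at 6 and 24 h at both glucose levels, and not at 2 h. If probes shared with other HSP70 transcripts were the cause, the 18 other features of the family were predicted to rise as much. The larger of their median rises at 6 h was 0.3562, against 3.43 and 3.76 for HSPA6. This median cannot decide the question, because the 18 features include relatives such as HSPA12A, HSPA13 and HSPA14, which need not rise with HSPA6. The maximum of 1.53 belonged to features of HSPA1A and HSPA1B, so none of the 18 rose as much as HSPA6. A contribution of their transcripts to the HSPA6 signal is not excluded. A difference between runs of culture numbers would have shrunk within single runs at 24 h, where the lowest difference was 2.00 (1 laser array against 2 controls). Whether the controls had the black paper and fresh medium is not stated, so an effect of this handling was not tested. A heat response of the cells to the laser is a candidate explanation and was found on the same data.

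CYP1A1 and CYP1B1 were higher in laser arrays at 24 h. The lowest of their differences within single runs of culture numbers was 0.94 (CYP1B1 at 22 mM, 3 against 2 arrays), where all arrays gave 1.17, which argues against the runs as the cause. Activation of the aryl hydrocarbon receptor might raise both genes, and then a list of 9 other targets of this receptor should have been higher, but its larger camera adjusted p was 0.864 (0.527 at 5 mM), while TIPARP rose at both levels (0.91 and 0.55) and, at 22 mM, NQO1 rose (0.83) and SLC7A5 fell (-0.44, adjusted p = 0.0279), so the list decides nothing. Substances from the black paper or the fresh medium could act on this receptor, and whether the controls had them is not stated, so this stays open.

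Chance was weighed by counting calls for other splits of the same arrays. By the rule set beforehand, a share of splits under 0.05 reaching the real count speaks against chance. For the laser effect at 6 h at 5 mM the share was 1 of 35, the real split (362, highest other 4). It was also 1 of 35 at 6 h at 22 mM (1291 against 491) and 24 h at 22 mM (1069 against 730). For glucose it was 1 of 35 at 6 h (116 against 1) and 24 h (152 against 15). For the change of the laser effect it was 3 of 100 from 2 to 6 h at 5 mM (26 against 441). From 2 to 24 h at 22 mM it was 4 of 100 (1487 against 5469). The shares were not adjusted for the number of comparisons, and the splits ignored the runs of culture numbers. At 6 h the real laser split is also a split by run, so laser and run cannot be told apart there. Chance was thus weighed apart from the runs. It cannot be excluded for the laser effect at 2 h at 22 mM (2 of 35; 136 against 1571) and at 24 h at 5 mM (3 of 35; 248 against 6335), for mannitol (2 of 35; 11 against 14), for the change from 2 to 24 h at 5 mM (5 of 100; 24 against 799) and from 2 to 6 h at 22 mM (6 of 100; 644 against 1401), and for glucose by laser at 6 h (5 of 100; 1 against 53). Where 0 features were called, every split reached that number, with highest others of 810 and 4038 for glucose by laser at 2 and 24 h (100 of 100 each), 1 for glucose at 2 h (35 of 35) and 173 for glucose against mannitol (35 of 35). The 10 splits of 3 against 3 arrays at 2 h at 5 mM are too few for a share under 0.05; the real split gave 30 and the highest other 0. Splits that call several times the real number point to a structure of the samples: the 6335 calls came from parting cultures 7, 8, 9 and 10 from cultures 28, 29, 54 and 55, and the 173, where the real split gave 0, from parting 32, 33, 37 and 39 from 58, 60, 67 and 68, both of them divisions by culture number. The 441 and 5469 calls were also several times the real number, and runs differ between times. The 14 calls for mannitol, near the real 11, came from parting 9, 10, 37 and 39 from 28, 29, 58 and 60. With the culture series as a block, the laser effect 5 mM 24 h gave 628 calls and the mannitol effect 24 h gave 5, and with runs as a block these were 39 and 600. Glucose at 24 h, for which the splits also ignored the runs, gave 29 and 11 with these blocks. The 1571 calls came from parting laser cultures 95, 96 and 99 with control culture 84 from the other 4 arrays.

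Single arrays stood apart from the other 3 of their group for some named genes, a test that marks about 1 in 20 groups by chance. Among controls of 22 mM this held for 2 named genes at 24 h, 5 at 2 h and 8 at 6 h (7 of these in replicate 2), and among controls of 5 mM for 2 at 24 h and 1 at 6 h; in mannitol it held for 0. Among laser arrays it held for 7 named genes at 24 h, 6 at 2 h and 13 at 6 h at 22 mM (11 of the last in culture 22), and for 2 at 24 h and 1 at 6 h at 5 mM. List means stood apart in 3 lists at 2 h and 3 at 6 h in controls of 22 mM, 1 at 24 h and 2 at 6 h in controls of 5 mM, 3 at 24 h, 2 at 2 h and 4 at 6 h in laser arrays of 22 mM (of the last, the unfolded protein, matrix and cholesterol lists in culture 22 and oxidative stress in culture 53), and 1 at 24 h and 1 at 6 h in laser arrays of 5 mM. Laser replicate 4 of 5 mM at 6 h had a median of 6.477, apart from the others of its group, and laser replicate 4 of 5 mM at 24 h stood apart in 6.24 percent of features.

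Effects that differed between groups by the test of the difference itself were 1 feature for glucose by laser at 6 h, ID2 with -1.27, and 26, 24, 644 and 1487 features whose laser effect changed with time (2 to 6 h and 2 to 24 h at 5 mM, then at 22 mM). Features left out of the tests also carried a signal. Of those shared by several genes, 4 and 10 passed at 2 h, 38 and 71 at 6 h, and 20 and 68 at 24 h (5 and 22 mM). Of those with no gene name, 15 and 31 passed at 2 h, 40 and 84 at 6 h, and 12 and 252 at 24 h.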

How the results depend on the processing

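Alternatives marked as added here (array median covariate, runs as a block, single runs, 6 h series block) were chosen after the data were seen. Named genes kept their side of the threshold in 4470 refits with other settings, lost the call in 748 and gained it in 15. Without single arrays these numbers were 4744, 1325 and 8. They include looked-up genes not called at first, whose sign can change. Lists kept their side in 182 refits with other settings and lost it in 148, and in 992 and 148 without single arrays. Of the numbers called, the following moved by more than 1.5 times. With only the groups compared the laser effects gave 13 (5 mM, 2 h), 62 (22 mM, 2 h), 1420 (laser effect 5 mM 6 h), 605 (22 mM, 6 h), 18 (5 mM, 24 h) and 498 (22 mM, 24 h), glucose by laser at 2 h 1, time by laser 5 mM 6 against 2 h 333 and 24 against 2 h 6, glucose 12 (6 h) and 0 (24 h) and mannitol 0. With all 50 arrays the 5 mM laser effects gave 47 (2 h), 1053 (6 h) and 462 (24 h), and time by laser at 5 mM 56 and 59. Centring gave 860 for the laser effect 22 mM 6 h, 23 for glucose at 6 h and 2 for glucose by laser at 6 h. Quantile normalization gave 554 for the laser at 5 mM at 6 h, 30 for glucose at 6 h and 2 for glucose by laser at 6 h. Leaving out the dimmest features gave 293 for the glucose effect 6 h, 281 for the glucose effect 24 h, 7 for mannitol and 2 for glucose by laser at 6 h. All complete features gave 50 for the laser at 5 mM at 2 h, 17 for mannitol and 2 for glucose against mannitol. The trend and robust option gave 182 for glucose at 6 h. The planned culture series block gave 628 for the laser effect 5 mM 24 h, 29 for glucose at 24 h, 5 for mannitol and 1 for glucose against mannitol. Culture numbers under 45, which leave fewer arrays, gave 12 for the laser at 5 mM at 24 h, 1 for glucose and 0 for mannitol. Among the added ones, the array median covariate gave 1009 and 1939 for the laser at 6 h at 5 and 22 mM, 476 and, for the laser effect 22 mM 24 h, 519 at 24 h, 446 for time by laser 22 mM 24 against 2 h, 3 for glucose by laser at 6 h, 83 for glucose at 24 h and 17 for mannitol. The series block gave 3 for glucose by laser at 6 h and was not estimable for the laser effects at 6 h. Runs as a block gave 39 for the laser at 5 mM at 24 h, 11 for glucose, 600 for the mannitol effect 24 h and 7 for glucose against mannitol. Within single runs the laser at 22 mM gave 38 (48 to 68), glucose 0 and mannitol 2295 (22 to 39), a run with 2 arrays per group. The cause of these changes was not tested.

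Without single arrays the laser numbers ran from 4 to 24 (5 mM, 2 h), 59 to 462 (22 mM, 2 h), 73 to 512 (5 mM, 6 h), 453 to 2021 (22 mM, 6 h), 97 to 339 (5 mM, 24 h) and 337 to 2667 (22 mM, 24 h). Time by laser ran from 5 to 46 and 8 to 93 at 5 mM and from 311 to 1332 and 412 to 4020 at 22 mM (6 and 24 h). Glucose ran from 0 to 0 (2 h), 23 to 189 (6 h) and 1 to 434 (24 h), mannitol from 0 to 14, glucose against mannitol from 0 to 0, and glucose by laser from 0 to 0, 1 to 1 and 0 to 0. The correlation between glucose levels ran from -0.237 to 0.00681 at 2 h, where it turned positive without control replicate 2 of 5 mM, from 0.663 to 0.760 at 6 h and from 0.328 to 0.750 at 24 h. For the numbers of calls no planned setting was left out, while lists and correlations were refitted with fewer settings. What depth limits could not be given, as signal over background was not stated. No paired analysis was possible, because the labels pair no arrays between groups, and replicate numbers give only the order within a group.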

Other observations

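HSPA1A and HSPA1B share their 5 features on this array, so they were not tested as single genes. They were looked up after the HSPA6 values were seen. All 5 features were higher in laser arrays at 6 h, by 1.44 to 1.53 at 5 mM (limma adjusted p from 1.30e-08 to 1.63e-08 over all complete features) and by 1.23 to 1.26 at 22 mM (2.24e-09 to 7.73e-09). The heat-inducible HSP70 members thus moved together at 6 h, with HSPA6 showing the larger change. Also chosen after the values were seen were 8 features called at both 6 and 24 h at both glucose levels. At 5 mM 9 called features rose at both times, 0 fell and 11 changed sign, and at 22 mM 19, 25 and 73. PLA2G4A rose each time (log2 1.01 and 0.67 at 6 h, 0.97 and 1.20 at 24 h, at 5 and 22 mM). HSPA6, SPRY2, ARMC9 and TIPARP did too. SEMA3A was lower at 6 h (-0.71 and -1.06) and higher at 24 h (0.74 and 0.46), as were KRT34 and KCNQ5. The 6 h values are relative to controls of a separate run.

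Lists added after the data were seen were tested on the arrays that led to them, so their p-values are no independent test. Clock genes were higher at 2 h at 5 mM (median 0.223, 2 of 16 rose and 5 adjusted over the list alone; adjusted p = 1.78e-08), and this call held with an estimated correlation (adjusted p = 1.61e-04). The circadian repressors NR1D1 (0.74 ± 0.13 at 5 mM and 0.58 ± 0.11 at 22 mM) and NR1D2 (0.59 ± 0.11 and 0.46 ± 0.09) rose at both levels and NFIL3 at 22 mM (0.53 ± 0.10), where the list did not pass (median 0.126, 3 rose and 3 up and 2 down adjusted over the list alone; adjusted p = 0.187). The laser effect on this list was smaller at 22 mM (median difference -0.150, adjusted p = 0.0101; adjusted p = 0.0341 with an estimated correlation). Genes with a ZNF (zinc finger) symbol were lower at 2 h at 22 mM. Of 494, 34 fell and 1 rose, against 107 and 7 adjusted over the list alone (median -0.143; adjusted p = 5.08e-22; adjusted p = 0.0226 with an estimated correlation). At 5 mM at 2 h this list did not pass (median -0.0331, adjusted p = 0.287, 1 fell over all genes, and 2 up and 1 down adjusted over the list alone). At 6 h the ZNF list was higher at 5 mM (median 0.0939, 12 rose and 1 fell, and 13 and 1 adjusted over the list alone; adjusted p = 3.90e-05; adjusted p = 0.396 with an estimated correlation). Its mean was 6.290 in laser replicate 4, 6.119 to 6.134 in the others and 6.034 to 6.100 in controls. At 22 mM at 6 h members went both ways, 10 up and 5 down, or 1 and 3 adjusted over the list alone (median 0.0202, adjusted p = 0.00224, and adjusted p = 0.464 with an estimated correlation). At 24 h 3 rose at 5 mM, and 6 rose and 4 fell at 22 mM, against 0, and 1 up and 1 down, adjusted over the list alone. The 24 h medians were 0.0800 (adjusted p = 2.65e-04, and adjusted p = 0.446 with an estimated correlation) and 0.0115 (adjusted p = 0.0397, and adjusted p = 0.732 with an estimated correlation).

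Control groups also differed in CYP1A1, CYP1B1 and IL1B, a comparison outside the design and chosen after the values were seen. At 5 mM CYP1A1 control means were 4.98, 6.91 and 5.10 (2, 6 and 24 h), and at 22 mM 5.19, 7.22 and 5.41. Its laser difference at 2 and 6 h was 0.87 and 0.93 ± 0.18 at 5 mM (adjusted p = 0.159 and 0.0141). At 22 mM it was 0.36 and 0.27 (adjusted p = 0.293 and 0.358). CYP1B1 lay at 10.59 and 10.79 in 6 h controls of 5 and 22 mM, and at 10.38 and 10.45 in 24 h laser arrays. For IL1B these means were 5.61 and 5.64, and 5.625 and 6.05. The 6 h controls form a run of their own, so time and run were the same division.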
